A study of Homo sapiens with 15 samples.

How the data were processed

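The data were polyA-selected RNA sequencing of HCT116 cells from a directional library kit, with 3 libraries of WT and 3 of each of the clones KO-1 to KO-4. Per the labels these come from 3 independent experiments. Per the submitters' processing notes, reads were trimmed with cutadapt 2.0 and aligned with STAR 2.7.1a to hg38. The tool that counted junction reads and the test behind the p-values are not given in the sources used here. The authors deposited 1 table for each clone against WT, with 1 intron per line and a list of 3 libraries per cell. Per the file headers the tables hold raw counts of junction reads, over the exon-intron boundaries (retained) and across the intron (spliced). The deposited inclusion levels are fractions of retained reads after division by effective lengths, and the deposited difference is the mean level of the clone minus that of WT. The deposited effective lengths give the number of positions at which a read can show each form. The deposited p-values and FDR values are the authors' own per intron, from a test that was not named. The tables list 90007, 100612, 97525 and 101710 introns, each with at least 20 junction reads in every library and none without a retained or a spliced read, so the authors applied a filter, whose rule is not given. For each clone 99.7% of the coordinates were found in the annotation. The lists carry no replicate numbers, so libraries are named by the order listed.

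Retention levels were recomputed from counts and lengths. An intron was tested with a mean of at least 10 retained and 10 spliced reads per library, which left 18804, 23669, 21865 and 24269 introns. Each clone was set against the 3 WT libraries with a quasi-binomial model of retained and spliced reads. Its Pearson dispersion was moderated toward a trend on retained reads with limma 3.58.1 (squeezeVar, in R 4.3.3) and floored at 1, an F test gave two-sided p-values, and these were adjusted by Benjamini-Hochberg with a threshold of 0.05. This departs from the plan, which named a quasi-likelihood test for counts. That test takes 1 count per feature, and retention is a ratio of 2. The unit of a change is the log2 odds of retention, with its SE, beside the difference in percent.

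U12-type introns were to be called from the genome sequence, which was not used here because no genome was at hand. The genes of a fixed list of 51 stood in for them as planned. A sequence rule was added after the data were seen, for introns whose ends are covered by exons of other annotated transcripts. It allowed at most 1 mismatch in the first 8 bases and at most 2 at the branch site, sought in the last 40 bases. Of 111143 introns in any table, 18020 had both ends read (16.2%), of which 83 were U12-type and 17879 U2-type. An intron counted as having an annotated exon inside if any annotated exon, on either strand, overlapped it in full or in part. Transcripts annotated as retained introns were left out of this. Classes were compared by two-sided Fisher's exact tests, adjusted over the 4 clones, and with 10000 random sets of U2-type introns matched on retained reads. Introns alike in all 4 clones were counted beside the number that independent lists would share and beside 20 simulated sets of unchanged clones with shared WT libraries. The difference among clones was tested with the same quasi-binomial model over their 12 libraries. Gene lists were tested by two-sided Fisher's exact tests, adjusted over 64 tests. The 16 lists were the U12 gene list, the minor spliceosome, the major spliceosome, SR proteins, hnRNPs and CLK kinases, box C/D methylation machinery, snoRNA host genes, ribosomal proteins, MAPK signalling, nuclear transport, the Integrator complex, DNA repair and cell cycle, p53 targets, WNT signalling, mRNA decay and nuclear surveillance, interferon response, and colon epithelial and mesenchymal identity.

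The named introns followed a fixed rule, with at most 1 intron per gene in each part. It took the 10 with the largest median rise and the 10 with the largest median fall among those past the threshold in all 4 clones, or in at least 3 with 1 direction in all where fewer than 10 passed. It also took the 5 largest rises and 5 largest falls of each clone, the 10 U12-type introns with the smallest median adjusted p, and up to 4 introns of each list. The introns of 1 gene that the rule names are not reported here. The gene lists, the tests planned, the alternatives planned and this rule were fixed before the data were examined. Spliced reads were also summed per gene over introns listed for all 4 clones, for genes with a mean of at least 50 per library. They were scaled by the median ratio and tested with limma (eBayes with a trend). This gene-level comparison was not planned.

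The tests were tested on simulated data with no other change. Of introns changed 4-fold in odds, 79%, 71%, 75% and 77% were called for KO-1 to KO-4, and of those changed 2-fold 16%, 20%, 19% and 22%, so smaller changes were mostly not detectable at this depth. False calls made up between 2.94% and 5.00% of calls, and data with no change gave 0 calls, with 4.90% to 5.31% of introns at an unadjusted p of 0.05. The intron counts were simulated with the dispersion that the test itself had moderated and floored. These rates thus do not check the moderation, and introns with a wider spread than it allows were not simulated. The test among clones called 79% of introns changed 4-fold and 25% of those changed 2-fold. The gene-level test called 89% to 95% of genes changed 2-fold. Pairs of libraries of a group differed by a mean chi-square per intron of 1.49 to 2.87, so no library was a copy of another. Alternatives were other thresholds and filters, limma on log2 odds with 0.5 added to each count, the authors' p, centring, strict and lax U12 rules, other backgrounds and leaving out each library. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.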

Results

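Polyadenylated RNA was sequenced from HCT116 cells, a human colon cancer line, in 5 groups of 3 libraries each. The groups were the wild-type line (WT) and 4 clones labelled as lacking bktRNA1, named KO-1 to KO-4. The labels do not describe bktRNA1 further, and its level was not analysed here, so the genotypes rest on the labels. For every intron listed, reads over the exon-intron boundaries (retained reads) and reads spliced across the intron (spliced reads) had been counted. The retention level was the share of retained reads after scaling for the length of each form. Over the 83066 introns listed for all 4 clones, the WT libraries held 29084063, 34001726 and 28650487 junction reads. The KO-1 libraries held 19917557, 20454252 and 17287797, and those of KO-2 held 28507353, 31652052 and 35348260. For KO-3 the totals were 32275313, 31300815 and 27092050, and for KO-4 they were 32224249, 31743028 and 29487315. Retained reads made up between 12.3% and 13.7% of these totals. There was 1 WT line and each clone is 1 isolate, so a p-value speaks of that clone against this line and not of the genotype. Coordinates are in hg38, and values are means ± SD over 3 libraries unless an SE is named.

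The first question was which introns were retained differently in every clone. Retention was higher in all 4 clones for 42 introns of 37 genes and lower in all 4 for 2 introns, both of SPCS2, among the 18064 introns tested in every comparison. Intron 4 of 4 of CCDC43 (chromosome 17, 44679044 to 44680584) was retained at 6.22% ± 0.99 in WT (n = 3). It reached 42.2% ± 4.8, 38.2% ± 7.2, 32.4% ± 4.8 and 33.7% ± 1.2 in KO-1 to KO-4 (n = 3 each). CCDC84 (CENATAC), a protein of the minor spliceosome, rose in intron 5 of 10 (chromosome 11, 119011284 to 119011938). Its level was 19.9% ± 3.2 in WT and 41.5% ± 3.5, 49.3% ± 1.1, 48.2% ± 11 and 52.9% ± 3.3 in the clones. ATG3, the enzyme that conjugates LC3 to lipid in autophagy, rose in the last of its 11 introns (chromosome 3, 112532781 to 112534268). That intron went from 5.00% ± 0.93 to between 21.4% ± 2.8 in KO-4 and 35.8% ± 1.0 in KO-1.

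The other introns in the plot had the same direction. SRPK1, a kinase of splicing factors, rose in intron 6 (chromosome 6, 35874340 to 35886723) from 8.80% ± 1.2 to 21.2% to 31.3%. LSG1, a GTPase of ribosome assembly, rose in intron 10 (chromosome 3, 194648805 to 194650880) from 13.0% ± 2.3 to 28.2% to 38.3%. The palmitoyltransferase gene ZDHHC8 rose in intron 4 (chromosome 22, 20139893 to 20140114) from 48.9% ± 9.6 to 69.9% to 80.9%. CUEDC1 rose in intron 9 (chromosome 17, 57866545 to 57867356) from 35.2% ± 3.6 to 49.2% to 67.4%. TMEM41B, a lipid scramblase of the endoplasmic reticulum, rose in intron 4 (chromosome 11, 9287807 to 9288441) from 23.1% ± 5.8 to 36.5% to 43.4%. WDFY1 rose in intron 5 (chromosome 2, 223899071 to 223901182) from 11.2% ± 1.3 to 26.1% to 32.5%. In these 9 introns the log2 odds of retention changed by 0.84 ± 0.15 (SE, CUEDC1 in KO-4) to 3.44 ± 0.34 (CCDC43 in KO-1). Their adjusted p lay between 1.4e-15 and 0.019.

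**Figure D1:**
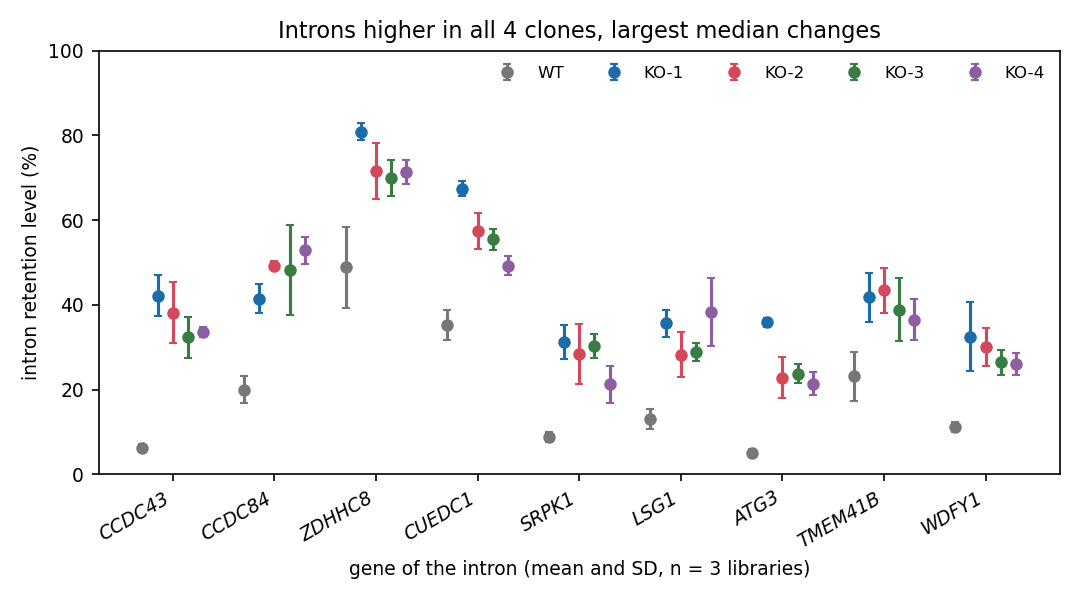
Retention level in percent (mean and SD, n = 3 libraries) of 9 introns with the largest median rises among those higher in all 4 clones, with WT and each clone in its own colour. WT levels run from 5.00% in ATG3 to 48.9% in ZDHHC8, and the mean of every clone lies above that of WT in each intron.

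Fewer introns fell in several clones. SPCS2, a subunit of the signal peptidase, fell in intron 2 of 3 (chromosome 11, 74965118 to 74969610) from 87.9% ± 2.1 in WT to 70.7% ± 4.3, 73.5% ± 2.3, 79.0% ± 3.9 and 78.8% ± 0.56 (n = 3 each). The other named introns passed in 3 clones and had a lower mean in the fourth without passing. Intron 1 of the helicase gene RECQL5 fell from 67.3% ± 11 to 34.7% ± 2.2 in KO-2 and 26.7% ± 4.3 in KO-4. The U12-type intron 7 of the elongation factor gene TCEA2 fell from 20.8% ± 2.5 to 4.91% ± 1.8 in KO-2. Intron 13 of the adhesion gene BCAM fell from 30.6% ± 7.7 to 19.0% ± 1.3 in KO-1. An intron of the splicing factor gene SRSF1 whose reads are shared with the overlapping AC015813.2 fell from 79.2% ± 2.1 to 71.3% ± 0.47 in KO-2. Intron 3 of HNRNPC, an RNA-binding protein gene, fell from 24.1% ± 0.46 to 19.7% ± 0.97 in KO-2. Past the threshold in at least 3 clones, with 1 direction in all 4, were 86 introns higher and 7 lower.

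Independent lists of these sizes would share 0.00036 introns higher in all 4 clones. Among 20 simulated sets of unchanged clones against shared WT libraries, the quasi-binomial test gave at most 0 introns in either direction. With no change a single simulated comparison also gave 0 calls, so this count does not measure what the shared WT libraries add among called introns. All 4 comparisons used the same 3 WT libraries, and the mean covariance of log2 odds changes between clones was 0.104 in the data against 0.0702 in the simulated sets. The correlations between clones, from 0.43 to 0.61, lay around the simulated 0.47, and changes had 1 sign in all clones for 39.4% of introns against 38.6%. The counts depended on the libraries, with 71 higher without the WT library listed 3rd, and 25 or 23 higher without the clone libraries listed 1st or 2nd. The lower count was 1 without the WT library listed 1st or 2nd or the clone libraries listed 1st or 2nd, and 0 without those listed 3rd. Limma on log2 odds called 2 higher and 0 lower, with 144 and 19 at an unadjusted p of 0.05 in every clone, where the quasi-binomial test had 179 and 27.

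A second comparison set introns of the U12-type class, which the minor spliceosome removes, against U2-type introns, which the major spliceosome removes. Among introns whose ends could be read, 25 of 56 U12-type introns (44.6%) were retained more in KO-1, 18 of 60 in KO-2, 19 of 60 (31.7%) in KO-3 and 16 of 59 (27.1%) in KO-4. The shares of U2-type introns were 0.987%, 1.38%, 0.364% and 1.89%. The odds ratios were 80.5 (95% interval 43.3 to 149), 30.6 (16.1 to 56.2), 126 (61.9 to 253) and 19.3 (9.94 to 35.8). Without the WT library listed 3rd they were 39.8, 14.8, 57.9 and 11.6, and without that listed 2nd 129 in KO-1, 57.7 in KO-2 and 34.4 in KO-4. Without the clone's library listed 1st they were 132, 51.4, 285 and 38.9, and without that listed 2nd 154 in KO-1, 47.7 in KO-2 and 39.5 in KO-4. Without the KO-1 library listed 3rd the ratio there was 130. The adjusted two-sided Fisher's exact p were 5.4e-33, 8.0e-19, 2.8e-29 and 2.7e-14. Lower retention was called in 1, 1, 1 and 2 of the U12-type introns. Introns are not independent replicates, so these p-values describe the introns listed.

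The introns of ATG3, LSG1, ZDHHC8 and WDFY1 above are U12-type and that of CUEDC1 is U2-type. Those of CCDC43, CCDC84, SRPK1 and TMEM41B could not be read at both ends, so their class is open. Of the 42 introns higher in all 4 clones, 14 were U12-type, 4 were U2-type and 23 could not be read at both ends. By the lax rule, which reads only the first 8 bases, 21 of the 27 that could be read there were U12-type. TMEM258, a subunit of the oligosaccharyltransferase, rose in intron 1 (chromosome 11, 61789922 to 61790492) from 3.48% ± 0.84 (n = 3) to 15.7% ± 2.8, 12.5% ± 1.5, 9.06% ± 2.2 and 8.53% ± 0.69 in KO-1 to KO-4. LSM8, which binds the U6 small nuclear RNA, rose in intron 1 (chromosome 7, 118184255 to 118185653) from 14.4% ± 2.8 to 39.2%, 28.8%, 32.1% and 25.7%. SNRPE, a core protein of spliceosomal snRNPs, rose in intron 1 (chromosome 1, 203861714 to 203862195) from 3.98% ± 0.14 to 7.14% to 9.96%. PSMA1, a proteasome subunit, rose in intron 5 (chromosome 11, 14513888 to 14514402) from 4.42% ± 0.46 to 12.9%, 9.45%, 8.22% and 7.21%. TRAPPC2L, of a vesicle tethering complex, rose in intron 2 from 8.47% ± 0.92 to 15.4% to 24.0%. PFDN5, a prefoldin subunit, rose in intron 3 from 2.74% ± 0.63 to 5.57% to 6.91%. UFD1, a cofactor of the p97 segregase, rose in intron 5 from 0.636% ± 0.49 to 4.55%, 2.23% and 2.28% in KO-1 to KO-3. In KO-4 that intron stood at 1.05% ± 0.22 and did not pass.

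**Figure D2:**
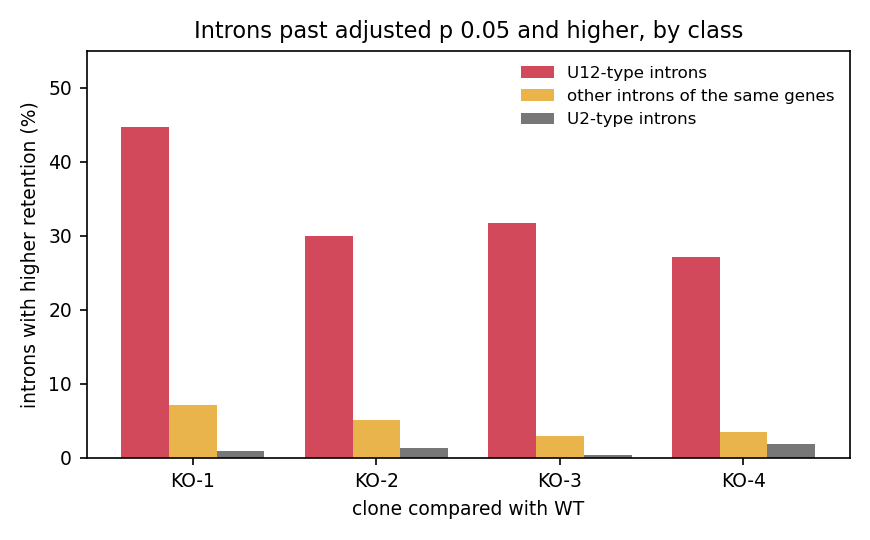
Percent of tested introns with higher retention at an adjusted p of 0.05, by clone, for U12-type introns, other introns of the same genes and U2-type introns. The U12-type bars run from 27.1% in KO-4 to 44.6% in KO-1, and the U2-type bars from 0.364% to 1.89%.

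Against other introns of the same genes the odds ratios were 10.3, 7.90, 15.3 and 9.97. In each clone the U12-type median change lay above all of 10000 sets of U2-type introns matched on retained reads. U12-type introns with GT-AG ends were higher in 21 of 42, 17 of 44, 17 of 45 and 13 of 44 cases, and those with AT-AC ends in 4 of 13, 1 of 15, 2 of 14 and 3 of 14. The AT-AC share in KO-2 did not pass (two-sided Fisher's exact p = 0.19). Called or not, 12 of 13, 14 of 15, 12 of 14 and 13 of 14 AT-AC introns had a change above 0. Their median log2 changes were 0.99, 0.54, 0.53 and 0.73, beside 1.16, 0.71, 0.67 and 0.68 for GT-AG introns. The genes of a fixed list, the planned stand-in for this class, had 19 of 112, 15 of 145, 11 of 138 and 11 of 154 introns higher. Their odds ratios were 16.8, 9.18, 16.9 and 5.03, with adjusted two-sided Fisher's exact p of 1.2e-15, 9.8e-10, 6.5e-10 and 2.8e-05. These shares passed with each library left out, though on fewer introns without some. In KO-1 they were 9 of 114 without its library listed 1st and 12 of 117 without that listed 2nd. In KO-2 they were 8 of 146 without the WT library listed 2nd and 8 of 142 without its own listed 1st. In KO-3 they were 6 of 142 and 5 of 144 without the WT libraries listed 1st and 2nd, and 6 of 135, 7 of 139 and 7 of 139 without its own in the order listed. In KO-4 they were 7 of 160 without the WT library listed 2nd, and 7 of 149 and 6 of 149 without its own listed 1st and 2nd. Without the WT library listed 3rd the odds ratios were 10.2 in KO-1, 5.48 in KO-2 and 2.41 in KO-4. With limma on log2 odds 7 of 56, 1 of 60, 2 of 60 and 1 of 59 sequence-called introns were higher, against 6, 1, 0 and 2 U2-type introns. These shares passed the threshold, though in KO-2 and KO-4 on 1 intron each. Limma called 0 introns of the gene list in KO-2, KO-3 or KO-4, where 33, 25 and 34 were higher at an unadjusted p of 0.05.

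Lower retention was also more frequent in this list than outside it. It was called in 3, 2, 3 and 3 of these introns, or 2.68%, 1.38%, 2.17% and 1.95%, against 0.160%, 0.298%, 0.143% and 0.419% of the others. The adjusted two-sided Fisher's exact p were 0.0026 in KO-1, 0.072 in KO-2, 0.0026 in KO-3 and 0.038 in KO-4, so the share in KO-2 did not pass. The introns were a pair in SPCS2 that share their start in all 4 clones, 1 in NCBP2 in KO-1 and KO-3 and 1 in MAPK9 in KO-4, of which NCBP2 and MAPK9 were chosen after their values were seen. By the sequence rule the SPCS2 intron from 74965118 to 74969610 is U2-type, and only that of MAPK9 was called U12-type. The list counts every intron of its genes, so these shares are not shares of U12-type introns. Retention in NCBP2 (chromosome 3, 196937632 to 196939392) fell from 91.7% ± 1.0 (n = 3) to 83.3% ± 1.9 and 83.3% ± 0.41, and in MAPK9 (chromosome 5, 180242756 to 180247438) from 10.6% ± 2.6 to 5.25% ± 0.97. Only KO-1 passed with each library left out. In KO-3 the share was 1 of 144 without the WT library listed 2nd (adjusted Fisher's exact p = 0.21). It was 2 of 142 without that listed 1st, and 2 of 139 without each of its own listed 2nd and 3rd. In KO-4 the adjusted Fisher's exact p was 0.36, 0.18 and 0.063 without the WT libraries in the order listed, and 0.25 and 0.43 without its own listed 2nd and 3rd, with 1, 2, 3, 1 and 1 introns lower. In KO-2 the share passed without its own listed 1st (exact p = 0.047) and 2nd (exact p = 0.042). The share in KO-4 did not pass when centred, with no filter, with a mean of 50 counts or by the authors' deposited adjusted p (adjusted Fisher's exact p = 0.14, 0.18, 0.20 and 0.11), and those in KO-3 and KO-4 did not when introns were called at an adjusted p of 0.01 (0.14 and 0.28). With a mean of 50 counts KO-2 passed (0.023). Limma on log2 odds called 0 introns of the list lower, where 4, 6, 5 and 6 were lower at an unadjusted p of 0.05. Each of the introns called has an annotated exon inside.

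A value per library was the median log2 odds of 56 U12-type introns minus that of 7316 U2-type introns, relative to WT. It was 1.01 ± 0.18 in KO-1 (SD, n = 3), 0.62 ± 0.03 in KO-2, 0.65 ± 0.12 in KO-3 and 0.58 ± 0.02 in KO-4, and the SD in WT was 0.09. Every clone library lay above every WT library. The two-sided exact permutation p was 0.1 for each clone, which is the smallest that 3 against 3 libraries allow. The U2-type median alone averaged 0.115, 0.090, 0.004 and 0.155 in KO-1 to KO-4, relative to WT. Its SD over the WT libraries was 0.185, so these general shifts lay within the spread of WT.

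**Figure D3:**
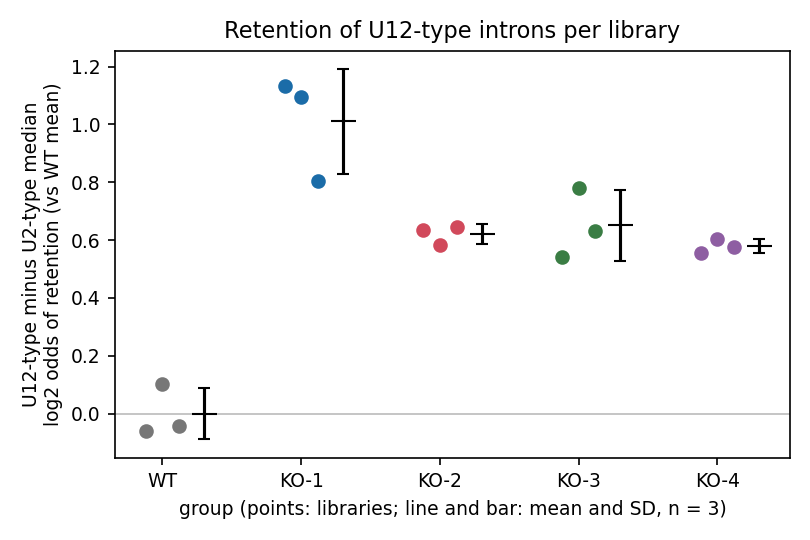
Difference between the median log2 odds of retention of U12-type and U2-type introns in each library, relative to the WT mean, with the mean and SD of each group (n = 3). The clone means run from 0.58 in KO-4 to 1.01 in KO-1, and every clone library lies above every WT library.

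The next 4 comparisons asked what each clone changed against WT. Of 198 calls of named introns only 55 lie in introns with no annotated exon inside. Part of the others could be other transcript forms and not retention. KO-1 gave 243 introns with higher and 33 with lower retention of 18804 tested. CCDC43 rose in a further intron, intron 3, from 10.5% ± 1.5 to 49.5% ± 2.8 (n = 3 each). The adhesion receptor gene CD44 rose in intron 4 of 5 (chromosome 11, 35190066 to 35201081) from 43.2% ± 3.9 to 82.8% ± 13. The rRNA methyltransferase gene BUD23 rose from 18.9% ± 3.8 to 56.2% ± 8.1, TM2D1 from 19.0% ± 3.7 to 52.8% ± 10 and the receptor gene FGFR1 from 52.2% ± 9.8 to 85.8% ± 3.5. Retention fell in ARHGEF11 from 73.0% ± 15 to 35.7% ± 9.8, and in the ribosomal protein gene RPL18 from 58.8% ± 1.2 to 25% ± 8.3. It also fell in CAP2 (45.3% ± 13 to 20.6% ± 4.1), FAM122B (55.9% ± 3.4 to 33.7% ± 8.4) and ANAPC4, of the anaphase-promoting complex (35.0% ± 4.3 to 15.2% ± 1.2). Adjusted p in these 10 introns ran from 8.4e-13 to 0.049. Centred on the median intron, which had moved by 0.13, the split was 140 higher and 56 lower, and limma on log2 odds called 41 and 1. Without the WT libraries listed 2nd and 3rd 160 and 522 were higher, with 51 lower without the former, and without the KO-1 libraries in the order listed 97, 119 and 153 were higher and 15, 14 and 14 lower.

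KO-2 against WT gave 307 higher and 72 lower of 23669 introns. The deubiquitinase gene USP10 rose in intron 2 (chromosome 16, 84733504 to 84758715) from 14.2% ± 2.7 to 73.4% ± 16 (n = 3 each). The keratin gene KRT15 rose in intron 1 (chromosome 17, 41518462 to 41521684) from 31.3% ± 4.7 to 80.4% ± 1.8. The sugar transporter gene SLC50A1 rose from 27.5% ± 5.5 to 66.0% ± 14 and TMEM132A from 24.5% ± 9.8 to 61.6% ± 22. TRIM62 rose from 0.457% ± 0.79, with 1 retained read in all of WT, to 38.4% ± 8.7. Retention fell in RECQL5, in the peroxisomal protease gene LONP2 (86.5% ± 7.3 to 57.2% ± 6.3) and in ACSL5, of fatty acid activation (43.5% ± 5.5 to 16.4% ± 5.5). It also fell in the kinase genes MKNK2 (54.2% ± 1.9 to 27.3% ± 2.6) and MAPK11 (38.4% ± 12 to 16.0% ± 5.6). Adjusted p in these 10 ran from 2.4e-09 to 0.025. The centred split was 198 higher and 133 lower, with a median shift of 0.09, and limma on log2 odds called 7 and 2. Without the WT library listed 2nd or 3rd 137 or 601 were higher, and without the KO-2 library listed 1st or 2nd 155 or 179, with 45 lower without the latter.

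KO-3 against WT gave 122 higher and 34 lower of 21865 introns. PHIP rose in intron 31 (chromosome 6, 78958601 to 78961689) from 10.5% ± 3.0 to 65.3% ± 7.9 (n = 3 each). SESTD1 rose in intron 4 (chromosome 2, 179172234 to 179176447) from 4.15% ± 1.5 to 46.8% ± 14. SEC31A, of COPII vesicles, rose from 21.7% ± 4.6 to 61.7% ± 13 and ICE1, of the little elongation complex, from 9.64% ± 4.9 to 49.5% ± 8.5, beside CCDC84. Retention fell in RECQL5, in the snoRNA host gene SNHG1 (70.9% ± 8.0 to 56.9% ± 4.1) and in the U12-type intron 21 of EDC4, an mRNA decapping factor (21.6% ± 4.0 to 10.7% ± 3.5). It also fell in the kinase gene PBK (62.5% ± 4.0 to 52.6% ± 1.6) and in FDPS, of isoprenoid synthesis (84.0% ± 0.83 to 74.2% ± 1.7). Adjusted p ran from 2.8e-10 to 0.041. The centred split was 92 higher and 33 lower, with a median shift of 0.02, and limma on log2 odds called 12 and 1. Leaving out the WT libraries in the order listed gave 73, 73 and 208 higher, and leaving out the KO-3 library listed 1st or 2nd gave 60 or 71 higher, with 15 lower without the former.

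KO-4 against WT gave 374 higher and 104 lower of 24269 introns. MID1, a ubiquitin ligase of microtubules, rose in intron 1 (chromosome X, 10567604 to 10620289) from 1.42% ± 1.2, with 7 retained reads in WT, to 83.7% ± 9.1 (n = 3 each). CD44 rose in intron 3 of 6 of a transcript (chromosome 11, 35210055 to 35214851; 37.3% ± 6.6 to 74.9% ± 6.2) and fell in the intron from 35190066 to 35211245 (85.0% ± 7.3 to 50.7% ± 3.4). TIMM17B, of mitochondrial import, rose from 12.8% ± 4.2 to 50.7% ± 23. The unnamed loci AC092143.3 and AC012363.1 rose from 32.6% ± 13 to 73.4% ± 17 and from 18.4% ± 12 to 54.3% ± 12. Retention fell in RECQL5, the cadherin gene FAT1 (59.1% ± 5.5 to 28.2% ± 3.1), CAP2 (45.3% ± 13 to 17.8% ± 2.8) and MAD2L2, of DNA repair (56.6% ± 12 to 29.1% ± 1.0). Adjusted p ran from 6.0e-22 to 0.023. Centred on the median intron, which had moved by 0.16, the split turned over to 126 higher and 179 lower, and limma on log2 odds called 8 higher and 0 lower, with 2146 and 588 at an unadjusted p of 0.05. Without the WT libraries in the order listed 218, 186 and 1045 were higher, and without the KO-4 libraries 167, 151 and 235, with 43 or 46 lower without the KO-4 library listed 1st or 2nd.

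The authors' deposited tables list 738, 1171, 534 and 1426 introns at an adjusted p of 0.05 for KO-1 to KO-4. Among the introns tested here they list 453, 788, 314 and 945, of which the quasi-binomial test also called 241, 332, 127 and 418. Retention differed among the 4 clones at an adjusted p of 0.05 for 1446 of 24385 introns, including 13 of the 42 higher in all clones.

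The last question was whether changed introns gathered in any of 16 lists of genes. In 13 of the 64 tests of a list in a clone, changed introns were more frequent in the list than outside it (two-sided Fisher's exact test, adjusted over all 64). These were the U12 gene list in all 4 clones, SR proteins, hnRNPs and CLK kinases in KO-1 and KO-2, and snoRNA host genes in KO-2, KO-3 and KO-4. The others were DNA repair and cell cycle in KO-1, p53 targets in KO-2, and the minor spliceosome and MAPK signalling in KO-4. Outside the U12 gene list, no test passed with a mean of at least 50 reads or with limma on log2 odds. Introns of a gene are not independent, and with 1 intron per gene only 3 of these tests outside the U12 gene list still passed: DNA repair and cell cycle in KO-1, SR proteins, hnRNPs and CLK kinases in KO-2, and snoRNA host genes in KO-3.

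Among splicing factors, SR proteins, hnRNPs and CLK kinases had 12, 17, 2 and 5 introns higher and 1, 2, 4 and 3 lower in KO-1 to KO-4, of 278, 297, 299 and 303. Adjusted over the list alone, the counts were 25, 28, 4 and 5 higher and 1, 6, 5 and 3 lower. HNRNPD rose in intron 8 from 5.27% ± 1.1 (n = 3) to 9.86% ± 0.77 in KO-2, and SRSF1 in intron 3 of 3 from 14.0% ± 1.1 to 18.8% ± 0.69. The minor spliceosome had 2, 2, 1 and 2 introns higher and 1 lower in KO-4, all in CCDC84. Adjusted over the list alone, it had 3, 2, 3 and 2 higher and 0, 1, 2 and 1 lower. The major spliceosome had 2, 3, 1 and 4 higher and 0, 0, 1 and 1 lower, and 2, 6, 1 and 7 higher and 0, 0, 1 and 2 lower adjusted over the list alone. There SNRNP70, of the U1 snRNP, rose in intron 7 from 7.66% ± 2.1 to 11.1% ± 0.35 in KO-1, 15.4% ± 2.7 in KO-2 and 12.1% ± 1.7 in KO-4, and stood at 7.94% ± 1.9 in KO-3.

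In genes of small RNA biology, snoRNA host genes had 4, 5, 1 and 10 introns higher and 4, 5, 9 and 5 lower of 210, 220, 218 and 217. Adjusted over the list alone, they had 4, 12, 2 and 17 higher and 5, 16, 17 and 8 lower. EIF4A2, a helicase of translation, rose in intron 10 from 45.5% ± 1.5 (n = 3) to 52.2% ± 0.90, 51.7% ± 2.2 and 51.8% ± 2.6 in KO-1 to KO-3. SNHG32 fell in intron 1 from 23.8% ± 3.3 to 18.4% ± 1.2 in KO-1 and 18.4% ± 0.73 in KO-4. Box C/D methylation machinery had 1, 3, 0 and 3 introns higher, all in NOP56, and 2, 4, 0 and 6 higher with 1 lower in KO-4 adjusted over the list alone. NOP56, a core protein of box C/D particles, rose in intron 4 from 16.3% ± 4.4 to 22.2% ± 1.7 in KO-1, 25.8% ± 4.8 in KO-2 and 30% ± 3.3 in KO-4, and stood at 16.2% ± 2.7 in KO-3. Ribosomal protein genes had 8, 9, 1 and 7 higher and 2, 2, 4 and 3 lower of 420, 454, 448 and 429, and 10, 10, 4 and 11 higher and 2, 2, 8 and 3 lower adjusted over the list alone. RPS9 rose in intron 3 from 36.1% ± 4.2 to 56.3% ± 7.5, 53% ± 4.4 and 52.3% ± 3.3 in KO-1, KO-2 and KO-4.

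In signalling and the cell cycle, MAPK signalling had 3, 3, 2 and 4 introns higher and 1 lower in KO-4, and 5, 3, 2 and 4 higher and 1, 0, 0 and 1 lower adjusted over the list alone. DNA repair and cell cycle had 6, 4, 3 and 2 higher, and 6, 7, 3 and 3 adjusted over the list alone. PARP1, a sensor of DNA breaks, rose in intron 22 from 0.265% ± 0.076 (n = 3) to 2.76% ± 0.89, 1.24% ± 0.54, 1.26% ± 0.50 and 1.33% ± 0.29. The transcription factor gene E2F6 rose in intron 5 from 2.29% ± 1.1 to 8.15% ± 3.4, 7.92% ± 2.0 and 8.41% ± 4.3 in KO-1 to KO-3. Nuclear transport had 3, 4, 1 and 3 higher, and 4, 5, 3 and 3 adjusted over the list alone. The exportin gene XPO5 rose in intron 24 from 4.09% ± 0.78 to between 9.32% ± 2.3 in KO-4 and 14.4% ± 2.5 in KO-1. The Integrator complex had 2, 2, 0 and 2 higher, and 2, 4, 0 and 2 adjusted over the list alone, and INTS3 rose in intron 4 from 6.80% ± 1.5 to 22.5% ± 5.3 in KO-2. The U12 gene list had 31, 22, 15 and 19 introns higher and 3, 3, 4 and 3 lower adjusted over the list alone. There DERL2, of protein degradation at the endoplasmic reticulum, rose in intron 4 from 10.7% ± 3.6 to 19.8% ± 1.3, 25.8% ± 5.9, 22.0% ± 2.6 and 21.3% ± 3.6.

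In the remaining lists few introns passed. p53 targets had 4 introns higher in KO-2, all in BAX, which were looked up after the count was seen, and 5 adjusted over the list alone. mRNA decay and nuclear surveillance had 1, 1, 0 and 3 higher, and 1, 1, 0 and 5 adjusted over the list alone, such as intron 15 of EXOSC10 in KO-4 (6.33% ± 1.0 to 11.1% ± 1.6, n = 3 each). Colon epithelial and mesenchymal identity had 1, 0, 1 and 1 higher and 2 lower in KO-4, and 1, 0, 1 and 1 higher and 2, 0, 0 and 3 lower adjusted over the list alone. KRT8 intron 1, at 99.1% ± 0.16 in WT, rose to 99.7% ± 0.10 in KO-3 and fell to 97.8% ± 0.095 in KO-4. WNT signalling and interferon response had 0 introns past the threshold by the quasi-binomial test or by limma in any clone, and adjusted over the list alone 1 for interferon response in KO-4. At an unadjusted p of 0.05 the quasi-binomial test had 3, 5, 2 and 5 higher and 0, 1, 0 and 1 lower for WNT signalling and 0, 2, 1 and 1 higher and 1, 0, 0 and 0 lower for interferon response. For p53 targets, which had 0 in KO-1, KO-3 and KO-4 by either test, those counts were 2, 0 and 3 higher and 0, 5 and 1 lower. In KO-3, where 0 passed by either test, the Integrator complex had 5 higher and 1 lower, mRNA decay and nuclear surveillance 4 and 1, and box C/D methylation machinery 0 and 0 (0 and 2 by limma). Colon epithelial and mesenchymal identity in KO-2, also with 0 by either test, had 2 higher and 0 lower.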

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

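All tests of an explanation in this part were chosen only after the result was seen, and the counts of other splits were planned. The clones differed from each other in the size of the U12-type rise. The median log2 odds of U12-type minus U2-type introns was 1.01, 0.62, 0.65 and 0.58 in KO-1 to KO-4 (n = 3 each). Of 15400 regroupings of the 12 clone libraries 180 gave as wide a range (exact permutation p = 0.0117). The KO-1 libraries held 17287797 to 20454252 junction reads, against 27092050 to 35348260 in the other clones. Whether depth adds to the difference among clones was not tested. Single introns were taken from the named ones that passed in at least 1 clone, by a quasi-binomial test of the difference among the 4 clones. The p in brackets below come from that test, adjusted over 24385 introns. U12-type introns differing among clones were those of PSMA1 (1.14e-10), UFD1 (9.71e-10), TMEM258 (3e-09), LSM8 (0.000391), ATG3 (0.000941), SNRPE (0.014) and TRAPPC2L (0.0286), each with its highest level in KO-1. CUEDC1 (6.84e-09) and PARP1 (0.0162) also stood highest in KO-1.

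Several named introns moved mainly in 1 clone, and the naming rule favours these because it took the largest changes of each clone. Among these were MID1 in KO-4 (9.45e-42), with 83.7% retained against 1.42% in WT, and in KO-3 SESTD1 (1.87e-26; 46.8% against 4.15%), PHIP (2.19e-23; 65.3% against 10.5%) and SEC31A (0.0277). KO-2 stood apart in KRT15 (1.52e-20; 80.4% against 31.3%), MKNK2 (7.35e-13) and LONP2 (0.000386). Against WT, MID1 and SESTD1 were tested in 1 clone only, and PHIP and LONP2 in 2. In the remaining clones these introns were not tested against WT. KO-4 stood apart in MAD2L2 (8.55e-11), and KO-1 in RPL18 (1.45e-05) and FAM122B (1.62e-10), the latter with a smaller fall in KO-2. FAT1 (8.84e-06) passed only in KO-4, with a median change of -13.8 points over the 4 clones. For CD44 the 2 introns starting at 35190066 (2.82e-14 and 2.34e-07) and that starting at 35210055 (0.011) differed.

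Some named introns in genes of splicing, translation and small RNA biology differed as well. Others of the same lists did not pass, such as those of DDX46 (0.41), NOLC1 (0.51) and EIF4A2 (0.40). No list was tested as a whole for a difference among clones. NOP56 (3.91e-23) reached 30% in KO-4 and 16.2% in KO-3, and SNRNP70 (9.03e-13) 15.4% in KO-2 and 7.94% in KO-3. HNRNPD (1.1e-10), HNRNPC (0.00322), the SRSF1 intron starting at 58005601 (0.00679) and that shared with AC015813.2 (0.00111) differed among clones. So did the ribosomal protein genes RPLP0 (4.54e-15), RPL4 (0.000155) and RPL36 (0.0377), and SNHG1 (5.26e-09), SNHG29 (2.74e-08) and RACK1 (0.00141). KRT8 (2.91e-16) rose in KO-3 and fell in KO-4, and KRT18 (5.77e-08), FDPS (1.27e-14), SHC1 (2.29e-07), BUD23 (0.00137), ARHGEF11 (0.000479), SLC50A1 (0.0232), RECQL5 (5.35e-05), PBK (0.000794), INTS3 (0.00149), SPCS2 (0.0106), E2F4 (0.0186) and NUP62 (0.0327) differed too.

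The higher retention of U12-type introns was weighed against 3 technical explanations. More reads from unspliced RNA or DNA, if spread over both classes alike, would raise matched U2-type introns as much. The U12-type median lay at percentile 100 of the matched sets in each clone, which argues against such an even rise. These sets were matched on retained reads and not on the WT retention level or the speed of splicing. They thus cannot exclude more unspliced RNA that raises U12-type introns more than U2-type introns, which stays open. Exons annotated inside the introns would leave nothing among introns without one, yet there the largest adjusted p over the clones was 2.06e-06. Noisier shares would spread the changes and not move their median, while the median over all tested U12-type introns, called or not, lay at percentile 100 of sets matched on retained reads and length too. Whether the rise comes from the loss of bktRNA1 or from a property of the WT line shared by all comparisons was not tested, and part of the overlap between clones may come from the shared WT libraries.

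Introns beside U12-type introns were also higher. In KO-1 and KO-2, 10 of 53 and 8 of 64 neighbours were higher against 2 of 115 and 3 of 152 other introns of these genes, which argues against a rise of whole genes (larger adjusted Fisher p 0.00624). In KO-3 and KO-4, with 4 of 63 and 5 of 66 against 2 of 144 and 3 of 159, neighbours and whole genes cannot be told apart (0.0710), as the counts are few. Exons inside the neighbours were argued against by 6 of 44 neighbours without one being higher, against 272 of 12275 other introns (Fisher p = 0.00043). No biological explanation was tested.

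Introns called in 1 clone only numbered 527, with a median of 59.96 retained reads, against 66.25 in the 245 introns called in several clones. This difference passed a two-sided Wilcoxon test (p = 0.0431, n = 527 and 245 introns). Introns with more reads are called more readily in several clones, and the median over all introns tested in every comparison was 27.92. The test thus does not decide whether some calls were missed in the other clones through low counts. Retention differed among the clones by the test of that difference for 303 of the 527 (57.5%). The 527 were chosen for passing in 1 clone on the same libraries, so this share cannot exclude low counts, which stay open. Alternative exons or transcript ends stay open too. An annotated exon overlapped 64.3% of the 527 introns, against 54.8% of the others (Fisher p = 1.55e-05). Part of these calls could thus be other transcript forms and not retention. No biological explanation was tested.

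The 6 libraries of a comparison make 10 splits, too few splits for a share under 0.05. The real split was the 1 of 10 with as many calls in each comparison. It gave 276, 379, 156 and 478 introns for KO-1 to KO-4, and the highest other split gave 0, 1, 2 and 1. For spliced reads per gene the real values were 1972, 4073, 2290 and 4632, and the highest other split gave 0 in each comparison by limma.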

How the results depend on the processing

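The settings tried only after the result was seen were the tests with limma on log2 odds, the authors' deposited adjusted p, centring and all settings at the gene level. The others were planned, among them leaving out each library, the authors' p readjusted, and the strict and lax U12 rules, though the way introns were read for these rules was added. No paired analysis was possible because the deposited lists do not number the replicates. The count tests planned with size factor and trimmed-mean scaling, their expression filter, and the pseudocount alternatives were not run, as retention is a ratio of 2 counts. Counts are given as higher for KO-1 to KO-4, then lower. At an adjusted p of 0.01 they were 134, 175, 68 and 156, then 12, 45, 18 and 51, with 27 and 0 in all 4 clones. With at least 10 points of change they were 103, 105, 46 and 119, then 20, 32, 3 and 49. With a mean of 50 counts, where fewer introns are tested, they were 73, 162, 49 and 216 higher, 16 lower in KO-1 and 18 in KO-3, and 18 and 1 in all 4. With no annotated exon inside, they were 90, 85, 45 and 130, then 2, 5, 8 and 23, and 17 and 0 in all 4. By the authors' deposited adjusted p they were 600, 222 and 786 higher in KO-2, KO-3 and KO-4, 90, 188, 92 and 159 lower, and 68 and 4 in all 4. With the authors' p, readjusted over the filtered introns, they were 566, 989, 370 and 1372, then 159, 375, 197 and 298, and 93 and 6 in all 4. With limma on log2 odds they were 41, 7, 12 and 8, then 1, 2, 1 and 0, and 2 and 0 in all 4, and the U12 gene list had 0% higher in KO-2, KO-3 and KO-4. Centred on the median intron they were 140, 198 and 126 higher in KO-1, KO-2 and KO-4, 56, 133 and 179 lower, and 4 lower in all 4. Beside the 0 counts, the unadjusted counts of 27 lower in all 4 by the quasi-binomial test, 19 by limma, and 588 lower in KO-4 and 33, 25 and 34 of the U12 gene list by limma stand. In at least 3 clones 86 were higher and 7 lower. Without KO-3 72 were higher and 6 lower in the other clones, and without KO-1 4 were lower. Of 64 list tests 13 passed, and 20 did with no filter on low counts, 4 of 62 with a mean of 50 counts, and of 64 again 7 with 1 intron per gene, 1 with limma on log2 odds and 8 by the authors' deposited adjusted p. In KO-2 6.67% of the AT-AC introns were called higher, a share no longer past the threshold. The U12-type minus U2-type median became 0.83, 0.47, 0.50 and 0.42 under the lax rule, 0.56 in KO-2 under the strict rule, and 0.57, 0.42 and 0.45 in KO-2, KO-3 and KO-4 with no annotated exon inside. Scaling by the total gave 597 genes higher and 1799 lower in KO-3. Leaving out 1 library at a time, the count of introns higher ran from 97 to 522 in KO-1, 137 to 601 in KO-2, 60 to 208 in KO-3 and 151 to 1045 in KO-4, the top of each without the WT library listed 3rd. The count lower ran from 14 to 51, 45 to 92, 15 to 49 and 43 to 126, and in all 4 clones from 23 to 71 higher and 0 to 3 lower. The U12-type minus U2-type median was 0.55 without the WT library listed 1st and 0.70 without that listed 2nd in KO-2, and ran from 0.48, without the former, to 0.60 in KO-4. Genes higher ran from 676, without the library listed 2nd, to 1010 in KO-1. In KO-3 they were 647 without the WT library listed 2nd, 736 without the KO-3 library listed 3rd and at most 982, and genes lower ran from 770, without that WT library, to 1035. The shares of sequence-called U12-type introns and of the U12 gene list higher stayed past the threshold with each library left out. Of 198 named calls, 30 stayed past the threshold with limma on log2 odds, 165 when centred, 171 by the authors' deposited adjusted p and 193 with no filter, and of 129 that could be compared 122 did with a mean of 50 counts. With no annotated exon inside only 55 could be compared, of which 50 stayed past the threshold. At this depth most introns changed 2-fold in odds were missed on simulated data, so counts say little of small changes. Apart from the filters that test fewer introns, the cause was not tested. No named call and no list test had the opposite direction past the threshold in the settings compared.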

Other observations

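The gene-level tests in this part were added to the plan, and the scaling by the median ratio was chosen only after the result with scaling by the total was seen, while the test of the retained intron itself was set before its result. Spliced reads per gene stand for transcript levels here (limma, n = 3 each, changes on the log2 scale with SE). In all 4 clones 106 genes were higher and 89 lower of 9376 tested, where independent lists would share 6.55 and 5.92. All comparisons used the same WT libraries, and 20 simulated sets of unchanged clones gave at most 0 by limma, so neither value measures what these libraries add among called genes. BMP4, a ligand of the TGF-beta family, rose by 0.77 to 1.65 over the clones, and DKK1, a secreted inhibitor of WNT signalling, by 0.83 to 1.40. The metallothionein gene MT2A rose by 0.57 to 1.46, the kinase gene PLK2 by 0.47 to 1.55, the gamma-tubulin gene TUBG2 by 0.44 to 1.07, OGDHL by 0.59 to 1.63 and LINC02331 by 0.85 to 1.16. IRF9, of interferon signalling, with reads shared with AL136295.5, rose by 0.64 to 2.22. CHPT1, of phosphatidylcholine synthesis, changed by -1.30 to -0.87, the hexokinase gene HK2 by -1.17 to -0.67 and HS3ST1, of heparan sulfate modification, by -1.72 to -0.59. CHPT1 and HS3ST1 each rest on 1 intron, with as few as 16 and 94 spliced reads in a library. For these 2 genes a change in transcript level cannot be told apart from one in splicing of that intron. ZDHHC2 changed by -0.92 to -0.48, the neuropeptide gene GAL by -0.89 to -0.53, ZPR1 by -1.01 to -0.59, MPP7 by -0.87 to -0.47 and the chromatin remodeller CHD3 by -1.21 to -0.41.

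Single clones had 1034, 2125, 1114 and 2347 genes higher and 938, 1948, 1176 and 2285 lower for KO-1 to KO-4. Genes for ribosomal proteins went apart: 55 of 81 were higher in KO-3 (median 0.26, 0.19 when scaled by the total) and 77 lower in KO-4 (median -0.36, -0.33 when scaled by the total). Interferon response genes were higher in KO-2 in 7 of 7 cases, with IFIT1 at 2.01 ± 0.22, ISG15 at 1.27 ± 0.12 and DDX58 at 1.14 ± 0.12, and in KO-4 in 5 of 7 (median 0.99 in KO-2 and 0.35 in KO-4, or 0.98 and 0.37 when scaled by the total). Nuclear transport genes were lower in 4, 20, 10 and 22 of 28 cases in KO-1 to KO-4, with medians of -0.04, -0.23, -0.09 and -0.24 (-0.05, -0.25, -0.16 and -0.21 when scaled by the total), and XPO4 stood at -0.75 ± 0.08 in KO-2 and -0.76 ± 0.09 in KO-4. Genes of box C/D methylation machinery were lower in 11 of 14 cases in KO-4 (NOLC1 -0.68 ± 0.05, FBL -0.49 ± 0.06) and 8 of 14 in KO-2, with medians of -0.12, -0.19, 0.06 and -0.25 in KO-1 to KO-4 (-0.13, -0.20, -0.01 and -0.23 when scaled by the total, which turns the direction in KO-3). The snoRNA host genes were lower in 16 of 23 cases in KO-4 and higher in 11 of 22 in KO-3 (medians -0.25 and 0.22, or -0.22 and 0.15 when scaled by the total). The p53 targets were lower in 9 of 15 cases in KO-4 (MDM2 -0.67 ± 0.07) and higher in 9 of 16 in KO-2 (CDKN1A 1.02 ± 0.06), with medians of 0.13, 0.21, 0.19 and -0.26 in KO-1 to KO-4 (0.12, 0.19, 0.12 and -0.23 when scaled by the total). EPCAM was lower in KO-1 (-1.06 ± 0.07), KO-2 (-0.99 ± 0.06) and KO-4 (-0.59 ± 0.09), and MYC in the same clones (-0.59 ± 0.10, -0.35 ± 0.08 and -0.77 ± 0.08). FN1 rose by 1.51 ± 0.11 and AXIN2 by 1.39 ± 0.10 in KO-4, and KRT8 and KRT18 by 0.53 ± 0.06 and 0.60 ± 0.07 in KO-3. These genes of the lists were chosen after their values were seen. The differences between clones at the gene level were not tested themselves. Scaled by the total, KO-3 had 597 genes higher and 1799 lower, with a median shift of -0.07. Without the library listed 2nd KO-1 had 676 higher. Without the WT library listed 2nd KO-3 had 647 higher and 770 lower, and without its own listed 3rd 736 higher.

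Genes with a sequence-called U12-type intron had slightly fewer spliced reads in KO-1 and KO-2, with median changes of -0.08 and -0.10 over 71 genes, at percentiles 0.10 and 0.47 of 10000 random sets of genes. The 95% ranges of these sets ran from -0.05 to 0.05 and from -0.07 to 0.07. In KO-3 and KO-4 the medians of -0.02 and -0.07 lay within the range of the random sets, at percentiles 9.26 and 5.05. Scaled by the total the medians were -0.09, -0.11, -0.09 and -0.05. Without the U12-type introns and their neighbours the medians were -0.02 over 63 genes in KO-1, -0.06 over 64 in KO-2, -0.01 over 63 in KO-3 and 0.02 over 63 in KO-4, at percentiles 26.25, 7.36, 29.76 and 67.70. The range of the random sets was then -0.06 to 0.05 in KO-1 and -0.08 to 0.07 in KO-2. In KO-1 the median moved close to that of the random sets. In KO-2 most of the change stayed, and it came to lie within a slightly wider range. A candidate explanation in KO-1 is that the loss of spliced reads lay in the retained intron itself and its neighbours. In KO-2 it would cover part of the change at most, and whether the whole transcripts were lower stays open in both clones.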
